A study of Brassica rapa with 12 samples.

How the data were processed

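Messenger RNA was sequenced from whole 2-week-old plants of Brassica rapa (Chinese cabbage) in 12 libraries, 3 for each combination of 2 genotypes and 2 temperatures. Total RNA was treated with DNase, made into libraries with a strand-specific mRNA kit (TruSeq Stranded mRNA LT) and sequenced on an Illumina NovaSeq system, per the labels' protocols. The authors deposited 1 table of counts per library, holding whole reads per gene with no normalization. FastQC, TopHat2, HTSeq and edgeR are named in the submitters' processing notes, without versions. The genome build, the annotation release and the strand setting of the counting were not given in the sources used here. Nothing in the labels says whether a library came from 1 plant or several, or whether replicates were grown separately, so p-values measure only the spread between these libraries, which may in part be technical.

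Each deposited table of counts listed the same 47249 gene IDs and 5 closing rows for reads given to no gene, which were kept out of library sizes and tests. The closing row for reads not aligned held 1.03 ± 0.00947 (SD over 12 libraries) times as many reads as all other rows together. Of those other reads, 90.8% ± 0.591 were counted in genes, 3.12% ± 0.328 lay outside genes, 3.55% ± 0.466 had more than 1 alignment, 1.50% ± 0.215 had a low alignment quality and 1.08% ± 0.0564 were ambiguous between genes. Total counts in genes ranged from 36778289 to 57777477 per library. At these totals a gene with 0 counts had a floor, set at 3 counts per library, of 0.0377 to 0.0964 CPM (counts scaled to a common library size). Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

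None of the gene IDs matched the gene table at hand, which lists 51589 genes of the assembly CAAS_Brap_v3.01, so genes are given by ID alone, with no symbol, function or coordinates. GIGANTEA and the 29 gene lists that had been fixed (among them heat shock proteins, clock genes and photosystem genes) were therefore not analysed here. The chromosome of a gene (A01 to A10) is the one its ID names, and the order of IDs was taken as the order along a chromosome, which is a naming convention not checked against a genome. Reads of near-identical gene copies, which are common in this formerly polyploid genome, may be split or lost by the counting.

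Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with its default minimum count of 10 and minimum total of 15, which left 28846 genes; 8678 genes had no count in any library. Libraries were scaled by TMM and 1 quasi-likelihood model with 4 group means was fitted to all 12 libraries (estimateDisp and glmQLFit, robust). The 5 contrasts were heat in each genotype, gi against wild type at each temperature, and the heat by genotype interaction. P-values from glmQLFTest were adjusted by Benjamini-Hochberg within each contrast, and genes under 0.05 were called. CPM values are TMM-scaled, and log2 fold changes are those of the model. Standard errors were obtained from the fold change and the F statistic.

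Genes named in the text were picked by a rule set before the data were examined. It took the largest log2 changes each way among called genes with a mean of at least 10 CPM in the higher group and no overlap between the libraries of the groups compared (overlap was allowed for the interaction). Because the IDs carry no names, 2 genes each way are given per contrast. Groups of 3 against 3 fail to overlap by chance for 10% of unchanged genes. Where a group had 0 counts, the fold is a lower bound against the floor of 3 counts per library; with 1 to 3 counts, the ratio is given with its exact 95% counting interval.

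Replicates of a group were compared by a chi-square of their counts over genes; the statistic per degree of freedom was 21.7 to 506 in the 12 pairs, so no library was counted as a duplicate of another. The procedure was tested on simulated data for 28320 genes, 100 changed by each fold size. For heat in gi, edgeR called 12% of 2-fold and 74% of 4-fold changes, and 8.51% of its calls were unchanged genes. For gi against wild type at 22 °C the values were 11%, 70% and 1.22%, and for the interaction 0%, 21% and 12.5%. DESeq2 1.42.0 called 29% and 91% for heat in gi, 32% and 88% at 22 °C, and 12% and 73% for the interaction. Unchanged genes made up 40.9%, 40.9% and 44.4% of its calls. In numbers, DESeq2 called 83, 83 and 68 unchanged genes and edgeR 8, 1 and 3. The shares depend on how few genes were changed in the simulation, so they do not carry over to the real lists.

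Replicate numbers come from the labels, which do not say what they mark. Deviations from the group means of libraries with the same number correlated at 0.285, 0.145 and 0.220 between gi and wild type at 22 °C and at 0.429, 0.152 and 0.221 at 37 °C, all over 0.1. Libraries with different numbers reached 0.0381 at 22 °C and 0.256 at 37 °C, so same-number pairs stood apart at 22 °C only. By the limit of 0.1, the numbers were taken to pair the libraries in these 2 contrasts. This was read per contrast only after the counts with the replicate block had been seen. The interaction is made of the same pairs, so its blocked counts are given too, although numbers did not pair libraries across temperatures. A block within each temperature was therefore added for these contrasts, also after the counts had been seen.

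Alternatives fixed before the data were examined were RLE scaling, scaling by total count, no filter, a filter of 1 CPM in 3 libraries, the DESeq2 Wald test, fits of the 2 groups compared alone, the replicate number as a block, and the removal of each library in turn. Counts without a stretch of chromosome A03, detection limits and all sets of heat-responsive genes were added after the data were examined. Sets of genes were tested with camera and fry of limma 3.58.1. For the smaller fall of strongly lowered genes in gi, the outcome that would count against it was reworded after its p-value had been seen, from a p above the threshold to a median of 0 or below. The draws for A03 were first read as counting against a heat response, and after their p-value had been seen were taken to leave it open. For the interaction, 2 of 100 groupings with as many genes were first read as excluding chance, which was withdrawn after all groupings that part the pairs had been run. The count with 1 library moved to the other genotype was added after the other splits had been seen.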

Results

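The transcriptome of wild-type Chinese cabbage (cultivar Chiifu) was compared with that of gi plants, in which GIGANTEA had been edited, with and without a short heat treatment. GIGANTEA is a plant protein of the circadian clock and of photoperiodic flowering, and the labels list the gi plants as late flowering and the wild type as early flowering. Plants were 2 weeks old and were either left at 22 °C or held at 37 °C for 1 h. Each of the 4 groups had 3 libraries. Total counts in genes averaged 51334353 in wild type at 22 °C, 45759614 in wild type at 37 °C, 46061810 in gi at 22 °C and 46420000 in gi at 37 °C, with a range over all 12 libraries of 36778289 to 57777477. The transcript level of the edited gene was not analysed here, because the gene IDs were not paired with names, so the genotypes rest on the labels.

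At 37 °C fewer genes took up more of the counts in both genotypes. The 100 most abundant genes of a library took 18.5% ± 4.53 (SD, n = 3) of the counts in wild type at 22 °C and 34.3% ± 0.502 at 37 °C. In gi these shares were 20.6% ± 1.72 at 22 °C and 33.5% ± 2.36 at 37 °C. In each genotype the 3 libraries at 37 °C lay above the 3 at 22 °C, for which a 2-sided exact permutation test of 3 against 3 gives p = 0.1, the smallest it allows. The 834 genes raised at least 8-fold by heat in both genotypes took 37.4% of the tested counts at 37 °C, against 1.36% at 22 °C. The TMM scaling factors were lower at 37 °C (0.719 ± 0.0489 in wild type, 0.816 ± 0.126 in gi) than at 22 °C (1.39 ± 0.134 and 1.25 ± 0.0598).

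In wild-type plants, 1 h at 37 °C raised 5241 and lowered 4771 of the 28846 genes tested. The changes were often large: 3465 genes rose and 3594 fell at least 2-fold, and 382 rose and 97 fell at least 32-fold. BraA10g017650.3.5C went from 0.204 ± 0.199 CPM (SD, n = 3) at 22 °C to 6075 ± 2331 CPM at 37 °C, a log2 change of 14.88 (SE 1.39, adjusted p = 1.95e-05). BraA05g014960.3.5C went from 0.102 ± 0.0821 to 1948 ± 396 CPM, a log2 change of 14.18 (SE 1.03, adjusted p = 2.90e-06). Among genes that fell, BraA03g046010.3.5C went from 12.1 ± 4.79 CPM to 0 counts in all 3 libraries at 37 °C, at least 132-fold lower against the floor of 3 counts per library (adjusted p = 0.00582). BraA03g049360.3.5C went from 11.6 ± 1.83 CPM to 0 counts, at least 126-fold lower (adjusted p = 1.21e-05). Both lie on chromosome A03 by their IDs. The first also had 0 counts in gi at 37 °C replicate 1, the second in no other library. Chromosome segments that differ between plants are a candidate explanation besides heat, so neither fall is shown to be a heat response. In gi at 37 °C the first had 0, 4.03 and 10.9 CPM in the 3 libraries, and the second 8.70 ± 3.58 CPM.

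The balance of rises and falls in wild type depended on the scaling. With total counts in place of TMM, the median log2 change of all genes was -1.05, against -0.11 with TMM, and 11.6% of the called genes were higher, against 52.3% with TMM. Without wild type at 37 °C replicate 1, 3178 genes were lower.

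In gi plants, heat raised 4685 and lowered 4082 genes. At least 2-fold changes were seen for 3429 genes that rose and 2777 that fell, and at least 32-fold changes for 392 and 33. The gene with the largest rise in wild type led here too: BraA10g017650.3.5C went from 0.224 ± 0.259 to 4595 ± 1151 CPM, a log2 change of 14.32 (SE 1.37, adjusted p = 2.68e-05). BraA03g011140.3.5C rose from 0.892 ± 0.791 to 11051 ± 3299 CPM, a log2 change of 13.59 (SE 1.11, adjusted p = 8.28e-06). BraA06g042770.3.5C fell from 13.8 ± 5.14 CPM to a single count over the 3 libraries at 37 °C, a ratio of 1539 (95% counting interval 276 to 60812, adjusted p = 3.22e-06), while the wild type had 15.5 ± 4.79 CPM at 37 °C. A chromosome segment that differs between plants is a candidate explanation here too, so this fall is not shown to be a heat response. BraA03g029310.3.5C fell to 2 counts (ratio 1123, 95% counting interval 311 to 9276, adjusted p = 0.00825), but its level at 22 °C varied from 0.0523 to 55.5 CPM between the 3 gi libraries, and without replicate 1 at 22 °C the ratio of means was 177.

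With total counts in place of TMM, the median log2 change of all genes was -0.68, against -0.07, and 18.5% of the called genes were higher, against 53.4% with TMM. The number of genes lowered was 2676 without gi at 22 °C replicate 2, 2596 without gi at 37 °C replicate 1 and 2460 without gi at 37 °C replicate 2.

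**Figure D1:**
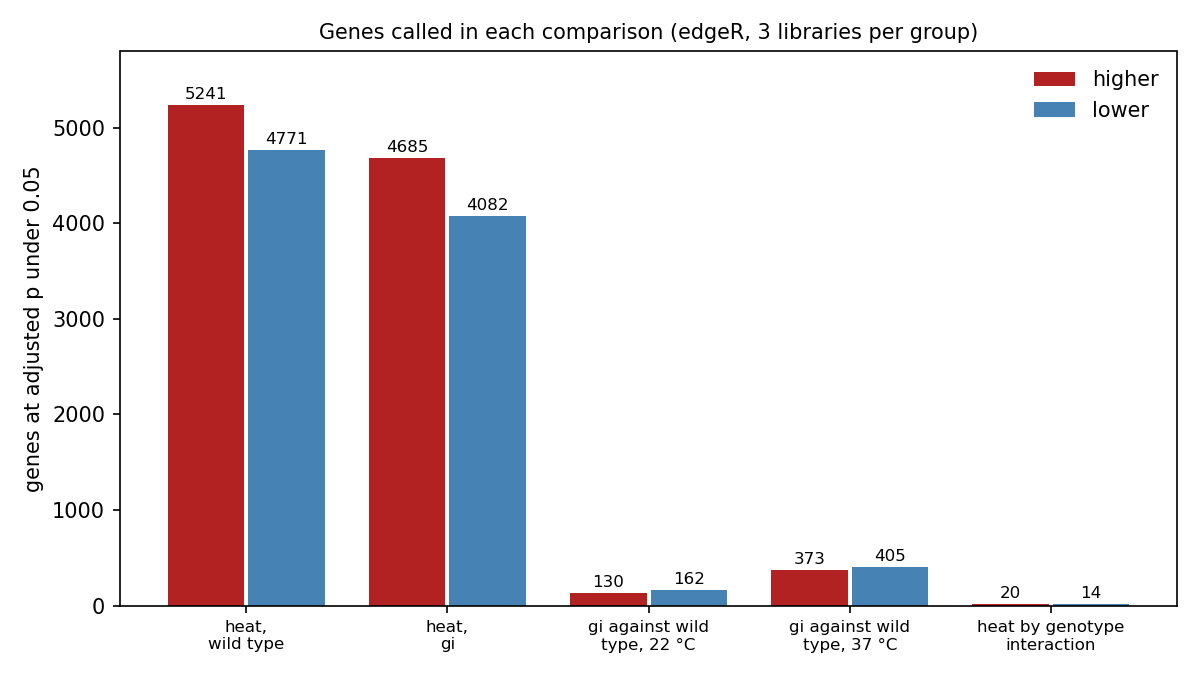
Numbers of genes called higher (red) and lower (blue) at adjusted p under 0.05 in each of the 5 contrasts, on a linear axis from 0. Heat called 5241 and 4771 genes in wild type and 4685 and 4082 in gi, genotype called 130 and 162 at 22 °C and 373 and 405 at 37 °C, and the interaction called 20 and 14.

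The heat responses of the 2 genotypes overlapped widely. In both genotypes, 3662 genes rose and 2584 fell, against 851 and 675 for independent lists of those sizes. Opposite directions were called for 19 genes, where independent lists would give 1517. Across genes, which are not independent replicates, the log2 changes of the 2 genotypes correlated with Pearson's r = 0.793 and Spearman's rho = 0.727, and the 2 contrasts share no libraries. The 3747 genes called in wild type alone and the 2502 called in gi alone are not thereby different between genotypes, which the interaction tests.

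The interaction, which tests whether heat changed a gene differently in gi and wild type, called 34 genes, 20 with a higher and 14 with a lower heat response in gi. All 34 differed at least 2-fold between genotypes in their response. Of the genes with a higher response in gi, BraA03g049360.3.5C had 11.6 ± 1.83 CPM at 22 °C and 0 counts at 37 °C in wild type, and 8.69 ± 4.40 and 8.70 ± 3.58 CPM in gi (adjusted p = 0.00299). BraA03g049540.3.5C went from 24.3 ± 10.4 CPM to a single count in wild type and from 15.7 ± 7.87 to 28.95 ± 9.54 CPM in gi (adjusted p = 0.00129). In the other direction, BraA06g032400.3.5C rose in wild type from 4.61 ± 2.96 to 275 ± 42.4 CPM but had 2.41 ± 0.355 and 2.17 ± 0.612 CPM in gi, an interaction log2 of -6.04 (SE 0.61, adjusted p = 0.00299). BraA06g042770.3.5C went from 25.3 ± 9.54 to 15.5 ± 4.79 CPM in wild type, and in gi fell as given above (interaction adjusted p = 0.00234).

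By chromosome, 18 of the 34 interaction genes lay on A03, which holds 14.7% of the genes tested, and 14 of the 20 with a higher response in gi did. An unadjusted p under 0.05 was found for 2945 genes, where 1442 would have it with no change, and on simulated data this contrast called 21% of 4-fold and 0% of 2-fold changes. Removing single libraries gave from 8 higher and 3 lower, without gi at 22 °C replicate 2, to 45 higher and 75 lower, without wild type at 22 °C replicate 1, and DESeq2 called 269 and 234. With the replicate block 10 genes were higher and 6 lower, and with a block within each temperature 5 and 4, when BraA03g049360.3.5C and BraA06g042770.3.5C were no longer called (edgeR adjusted p = 0.0717 for both). With total counts in place of TMM, the median of all genes was 0.34 in place of 0.01 and 80.6% of the called genes were higher, against 58.8%.

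**Figure D2:**
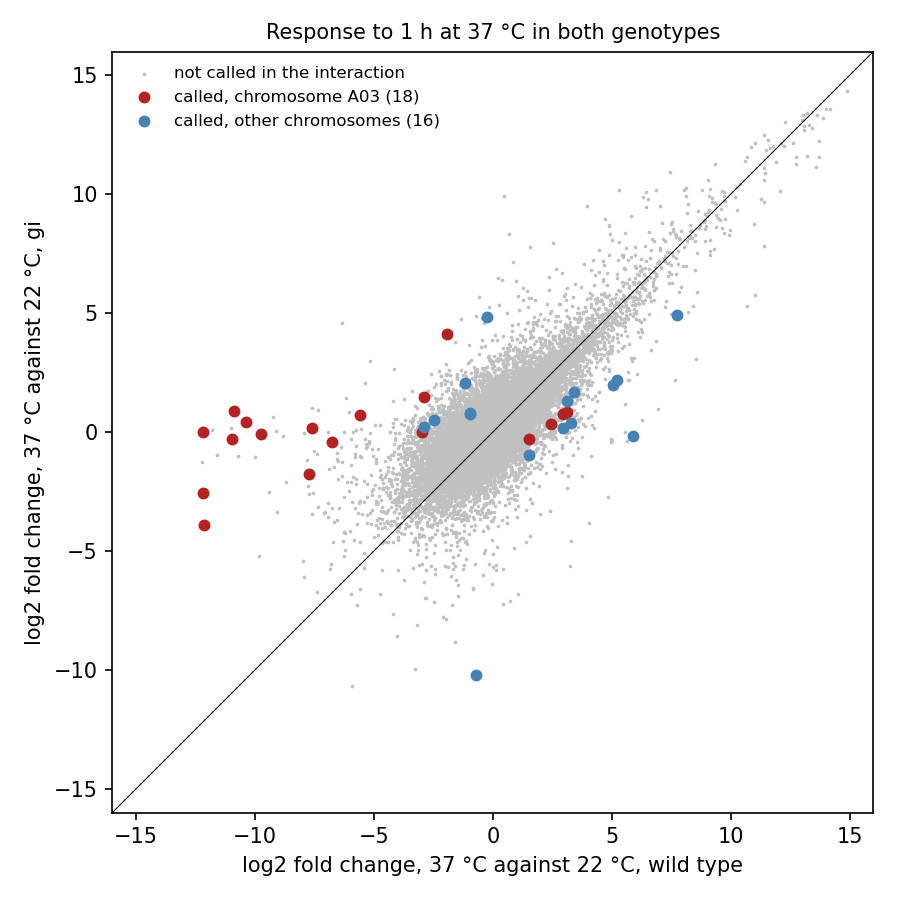
Log2 fold change from 22 °C to 37 °C in wild type (horizontal) against gi (vertical) for the 28846 genes tested; the line marks equal responses. Genes called in the interaction are red on chromosome A03 (18 genes) and blue elsewhere (16 genes); 14 of the 20 genes with a higher response in gi, which lie above the line, are red.

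Without heat, at 22 °C, 130 genes were called higher and 162 lower in gi, of which 34 and 81 by at least 8-fold. BraA06g010900.3.5C had 53.04 ± 11.03 CPM in gi and 0.0271 ± 0.0106 CPM in wild type, a log2 difference of 10.77 (SE 0.41, adjusted p = 1.04e-06). BraA06g022690.3.5C had 12.4 ± 2.37 and 0.0373 ± 0.0542 CPM, a log2 difference of 8.43 (SE 0.66, adjusted p = 0.000384). BraA09g062070.3.5C had 0 counts in gi at both temperatures and 59.3 ± 33.5 CPM in wild type at 22 °C, at least 1133-fold lower in gi (adjusted p = 0.00451). BraA09g062040.3.5C had 0 counts in gi and 34.7 ± 11.7 CPM in wild type, at least 664-fold lower (adjusted p = 0.000136). These A09 genes lie close together by their IDs, so they need not be separate effects. A linked segment that differs besides the edit was not excluded for them.

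With the replicate number as a block, which pairs these libraries, 74 genes were higher and 80 lower, and with a block within each temperature 40 and 58. Single libraries weighed on the counts without the block, which ranged from 34 higher and 50 lower, without gi at 22 °C replicate 2, to 432 and 291, without wild type at 22 °C replicate 1, and DESeq2 called 681 and 872. With total counts in place of TMM, the median of all genes was -0.17 in place of -0.02 and 30.4% of the called genes were higher, against 44.5%. On simulated data this contrast called 11% of 2-fold changes, so the counts are no measure of how many genes differ.

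After 1 h at 37 °C, 373 genes were higher and 405 lower in gi than in wild type, 316 and 297 of them by at least 2-fold. BraA03g061390.3.5C had 0 counts in wild type and 69.6 ± 63.0 CPM in gi, at least 757-fold higher (adjusted p = 0.00164), or at least 363-fold without gi at 37 °C replicate 1, which had 142 CPM. BraA06g010900.3.5C, also the leading gene at 22 °C, had 67.4 ± 14.9 CPM in gi and 1 count in wild type, a ratio of 6686 (95% counting interval 1200 to 264133, adjusted p = 1.31e-06). BraA03g026250.3.5C had 0 counts in gi and 30.3 ± 8.97 CPM in wild type, at least 370-fold lower (adjusted p = 0.00027). BraA09g062070.3.5C had 0 counts in gi and 23.6 ± 13.0 CPM in wild type, at least 288-fold lower (adjusted p = 0.00382).

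With the replicate block 276 genes were higher and 265 lower. The counts at 37 °C without the block ranged from 107 higher and 105 lower, without gi at 37 °C replicate 3, to 955 and 1039, without wild type at 22 °C replicate 1, and DESeq2 called 1438 and 1441. Wild type at 22 °C replicate 1 is outside this contrast and acts only through the fit shared by all 12 libraries. Its chi-squares per degree of freedom against the other replicates of its group were 506 and 454, against 96.2 between those. A fit of the 2 groups at 37 °C alone called 693 and 700. With total counts in place of TMM, the median of all genes was 0.16 in place of -0.02 and 76.0% of the called genes were higher, against 47.9%.

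The genotype difference overlapped between temperatures. In gi, 43 genes were higher and 109 lower at both temperatures, against 1.68 and 2.27 for independent lists, and edgeR called 0 genes in opposite directions, where DESeq2 called 19. The 152 genes called the same way became 92 with the replicate block, 67 with a block within each temperature (1 in opposite directions), 61 without gi at 22 °C replicate 2 and 279 without wild type at 22 °C replicate 1, where 9 went in opposite directions. Across genes the log2 differences at 22 °C and 37 °C correlated with Pearson's r = 0.600 and Spearman's rho = 0.336, and the 2 contrasts share no libraries. An unadjusted p under 0.05 was found for 4368 genes at 22 °C and 5871 at 37 °C, where 1442 would have it with no change.

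Some genes went from undetected to clearly detected between libraries. With limits chosen after the data were examined (under 0.1 CPM and at least 1 CPM), 276 genes were in one state or the other in every library and in both states over the 12 libraries. Of these, 33 genes on 9 chromosomes were undetected in the 6 libraries at 22 °C and detected in the 6 at 37 °C, and 0 showed the reverse. The 6 gi libraries lacked 16 genes that the 6 wild-type libraries had, and the wild type lacked 4 genes that gi had. The 6 genes undetected only in the 3 libraries of wild type at 37 °C all lay on A03. BraA03g051200.3.5C, which lies among them by its ID, was the 1 gene detected only in those libraries. BraA06g042770.3.5C was the 1 gene undetected only in the 3 gi libraries at 37 °C. The states of 215 genes differed between libraries of the same group, in a wild-type group for 205 genes and in a gi group for 40.

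**Figure D3:**
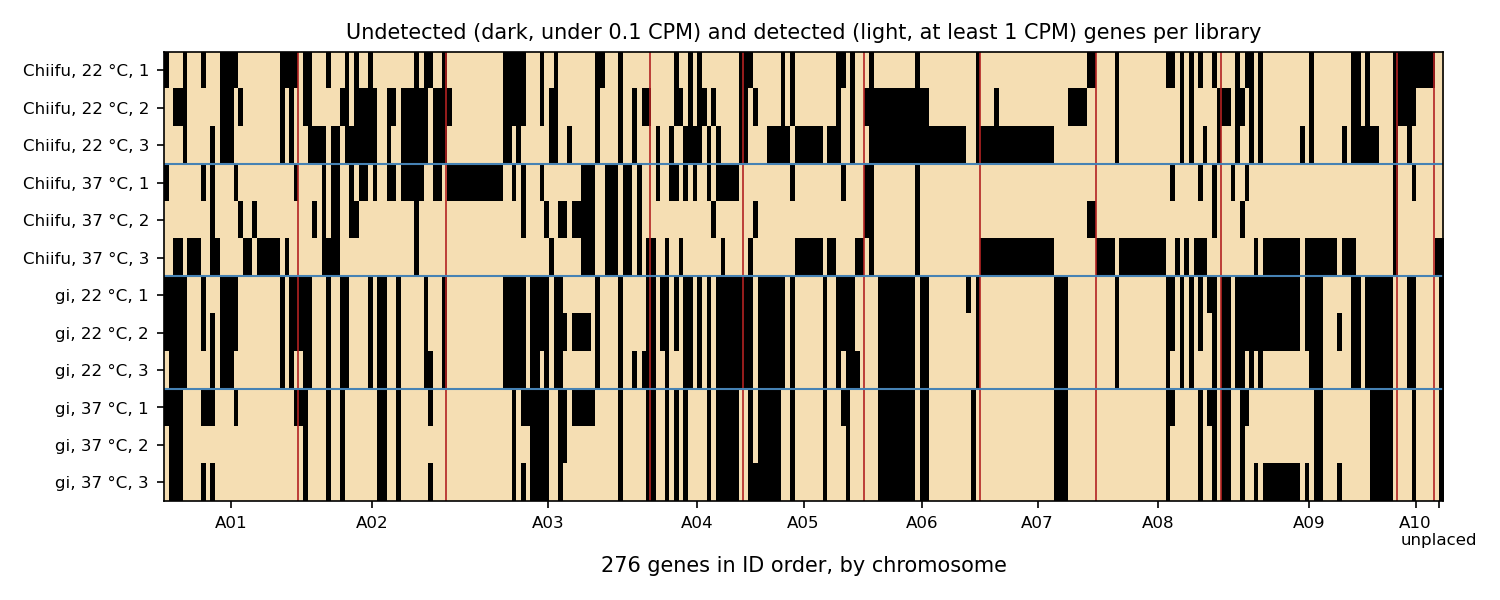
Detection of 276 genes (columns, in ID order by chromosome, red lines between chromosomes) in the 12 libraries (rows, blue lines between groups); dark cells are under 0.1 CPM and light cells at least 1 CPM. Runs of dark cells that stop within a group, such as those of wild type at 22 °C replicate 3, mark genes whose state differed between libraries of that group.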

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

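The draws for chromosome A03 and the groupings that part all pairs were chosen only after the interaction genes had been seen, and the A03 stretch was defined from the same data; the rotation test and the counts of other splits had been set before their results.

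The interaction was singled out because it tests a difference in heat response between genotypes: 20 genes responded more positively and 14 more negatively in gi than in wild type (edgeR). The named genes had interaction log2 values of 12.17 (BraA03g049360.3.5C), 11.78 (BraA03g049540.3.5C), -9.53 (BraA06g042770.3.5C) and -6.04 (BraA06g032400.3.5C). The values above 10 rest on wild-type groups at 0 or 1 count and that of BraA06g042770.3.5C on gi at 37 °C with 1 count, where the size depends on the prior count.

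Of 100 groupings drawn by permuting genotype within each temperature, 2 gave as many interaction genes as the real 34, the real one included; 60 had been drawn at first, also with 2. Of the 32 groupings that part all pairs of replicate numbers within temperatures, 2 did as well (2 of 32 also for the 9 genes of the block within temperature), so chance was not excluded. Most groupings also mix the genotypes, whose difference can then add to the spread and lower their counts, which was not tested. The other grouping called 1712 genes, or 1305 with the block within temperature. It swaps the genotypes at one temperature whole, so it measures the average genotype difference, a structure of the samples. Counted beside the real grouping, it held the share among the 32 at 0.0625, so these groupings could not have excluded chance. Of the 100, the 8 groupings that kept the real genotypes at 37 °C alone called 19 to 32 genes, close to the real count. The 8 that kept those at 22 °C alone called 0, and the 82 that kept neither called at most 7. The rest of the 32 called at most 33 genes, or 8 with the block within temperature, both where the genotypes at 37 °C were kept. Much of the interaction count can thus be reached from the genotype difference at 37 °C. For the other contrasts, 3 against 3 libraries make 10 splits, too few for a share under 0.05. In each, only the real split, 1 of 10, gave as many genes. The real counts and the highest of the other splits were 10012 and 19 for heat in wild type, 8767 and 12 for heat in gi, 292 and 5 for genotype at 22 °C, and 778 and 1 for genotype at 37 °C. Each other split mixes the real groups, so a large difference between them can add to the spread and lower the count. The gap to the real counts is therefore little support. Of the 4 genotype splits that part all 3 pairs of replicate numbers, the 3 others called at most 0 genes at 22 °C and 1 at 37 °C; the 6 that part fewer pairs called at most 5 and 0.

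Of the 20 genes with a higher response in gi, 14 lay on A03, and 11 lay in a stretch of 296 tested genes from BraA03g049360.3.5C to BraA03g054150.3.5C. In 9999 draws of 20 genes lowered by heat in gi, at most 10 fell on 1 chromosome (permutation p = 1e-04, the smallest the draws can give). This restates the gathering, and a heat response of the wild type that gi lacks stays open for linked genes. All 14 genes on A03 were called lower by heat in wild type. Any cause of low counts in wild type at 37 °C gives that call, so it speaks neither for nor against a heat response. Inside the stretch, BraA03g051200.3.5C, a single gene, was detected only in wild type at 37 °C. Before the stretch, BraA03g043730.3.5C and BraA03g044390.3.5C were undetected in wild type at 37 °C. They were also undetected in gi at 37 °C replicate 1 and in gi at 22 °C replicate 2, which was not heated. These genes lie outside the stretch and rest on single gi libraries, so they do not settle it. Another candidate explanation is a chromosome segment that differed between the wild-type plants at 37 °C and the other plants. Genes of the stretch that were not called had a median absolute interaction log2 of 0.66, against 0.44 on the rest of A03 (1-sided rotation permutation p = 0.0407), which is borderline, and is measured on a stretch picked for its extremes. The 16 interaction genes on other chromosomes stay open, and without the stretch 9 genes were higher.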

How the results depend on the processing

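Each alternative set before the data were examined was run except those of the gene lists and GIGANTEA, since no gene IDs were paired with names. Of 403 values of named genes under the alternatives, all kept their direction and 401 stayed past the threshold. The RLE scaling and both filters moved no count beyond 1.5 times.

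With scaling by total count, heat raised 2071 and lowered 15835 genes in wild type and raised 2520 and lowered 11075 in gi, with 11844 called the same way in both, which follows from the shift of all genes. Under it genotype called 80 higher at 22 °C and 727 higher and 229 lower at 37 °C, and the interaction 7 lower. The DESeq2 test called 681 higher and 872 lower at 22 °C, 1438 and 1441 at 37 °C, and 269 and 234 for the interaction, with 46 heat genes and 19 genotype genes in opposite directions and 538 genotype genes called the same way. These lists contained all of edgeR's 292, 778 and 34 genes. On simulated data DESeq2 called 68 to 83 unchanged genes. Those were 40.9% to 44.4% of its calls there, a share that depends on how few genes were changed and does not carry over to these lists. Fits of the 2 groups alone called 15 higher and 46 lower at 22 °C, 693 and 700 at 37 °C, and 36 genotype genes the same way at both. Without the A03 stretch, chosen after the data were examined, 9 interaction genes were higher. With limits also chosen afterwards, 289 genes (undetected under 0.2 CPM) or 125 genes (detected from 2 CPM) had states that differed within a group, against 215. With the second, 20 genes parted the temperatures, 9 were undetected in gi alone and 3 in wild type at 37 °C alone; with the first, 7 in wild type alone. Counts of 2-fold changes moved too, such as to 1701 higher for heat in wild type under total counts. Apart from total-count scaling, the cause was not tested.

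Replicate numbers did not pair the libraries across temperatures: 6 of 12 such same-number pairs had a correlation of deviations over 0.1 (range -0.32 to 0.26), and 7 of 12 libraries correlated best with their own number. With the replicate block, the interaction called 10 higher and 6 lower, and 12 heat genes went in opposite directions. Genotype called 74 higher and 80 lower at 22 °C and 276 and 265 at 37 °C, with 92 the same way, and no call of a named gene changed. With the replicate block within temperature, added afterwards, genotype called 40 and 58 at 22 °C, 67 the same way at both and 1 in opposite directions, and the interaction 5 and 4, without 2 named genes.

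Without 1 library, heat raised 4172 to 5289 and lowered 3178 to 4861 genes in wild type, and raised 3618 to 5385 and lowered 2460 to 5229 in gi, with 4834 to 6558 called the same way and 8 to 56 in opposite directions. Genotype called 34 to 432 higher and 50 to 291 lower at 22 °C and 107 to 955 higher and 105 to 1039 lower at 37 °C, with 61 to 279 the same way at both and 0 to 9 in opposite directions. The interaction called 8 to 45 higher and 3 to 75 lower. The highest genotype and interaction counts came without wild type at 22 °C replicate 1. Without the library that held its single count, the fold was at least 161 for BraA06g042770.3.5C (heat in gi) and 735 for BraA06g010900.3.5C (37 °C).

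Where a higher or lower count moved beyond 1.5 times, both were, for genotype at 22 °C, 46 and 63 without gi 22 °C replicate 1, 34 and 50 without gi 22 °C replicate 2, 58 and 95 without gi 37 °C replicate 2, 60 and 92 without gi 37 °C replicate 3, 432 and 291 without wild type 22 °C replicate 1, 69 and 92 without wild type 22 °C replicate 2, 83 and 123 without wild type 22 °C replicate 3, 82 and 116 without wild type 37 °C replicate 1. For genotype at 37 °C they were 226 and 216 without gi 22 °C replicate 2, 301 and 265 without gi 22 °C replicate 3, 126 and 167 without gi 37 °C replicate 1, 156 higher, 56.1% of those called, without gi 37 °C replicate 2, 107 and 105 without gi 37 °C replicate 3, 955 and 1039 without wild type 22 °C replicate 1, 132 and 186 without wild type 37 °C replicate 1, 120 and 253 without wild type 37 °C replicate 2, 241 and 301 without wild type 37 °C replicate 3. For the interaction they were 10 and 6 without gi 22 °C replicate 1, 8 and 3 without gi 22 °C replicate 2, 12 and 6 without gi 37 °C replicate 1, 11 and 3 without gi 37 °C replicate 2, 11 and 3 without gi 37 °C replicate 3, 45 and 75 without wild type 22 °C replicate 1, 16 and 22 without wild type 22 °C replicate 2, 12 and 5 without wild type 37 °C replicate 1, 14 and 8 without wild type 37 °C replicate 2, 13 and 9 without wild type 37 °C replicate 3.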

Other observations

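The shuffles of detection states, the count of genes parting the genotypes and the tests of heat-defined gene sets were chosen only after the results had been seen; the tests of scaling and of neighbouring genotype calls were set before.

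The 215 genes detected in some libraries and undetected in others of the same group came in runs along the chromosomes. Of 204 neighbouring pairs of such genes, 104 had the same set of undetected libraries, against a mean of 10.9 and a maximum of 24 in 9999 shuffles (permutation p = 1e-04, the smallest they can give), and with genes at least 5 places apart 79 pairs did, against a mean of 8.55. This argues against failed detection of scattered low genes, whose median level in detecting libraries was 5.04 CPM. A library with the wrong genotype is argued against by 20 genes that part all gi from all wild-type libraries, where no other split of 6 against 6 libraries that is not by temperature had more than 1 and moving any 1 library to the other genotype left at most 5. What fits is that plants of one group may carry different chromosome segments, for example 34 genes undetected in wild type at 37 °C replicate 3 alone, 17 of them on A08; contamination by other seed or a mixed seed stock was not tested.

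Genes called between genotypes were also neighbours more often than chance. At 37 °C, 43 called genes were followed by a gene called in the same direction, against a mean of 13.5 and at most 27 in 9999 draws of as many heat-responsive genes (permutation p = 1e-04, the smallest they can give). At 22 °C the number was 25, against a mean of 1.91. For the 34 interaction genes it was 0, against a mean of 0.0231 (permutation p = 1). So few neighbours are expected among 34 genes that a 0 cannot show an absence of linkage. Linked segments that differ between the gi and wild-type plants, besides the edit itself, may account for part of the genotype calls, which these libraries cannot separate from effects of GIGANTEA; tandem copies that respond together are matched by the draws only as far as they respond to heat.

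The lower scaling factors at 37 °C went with the heat-raised genes: the mean log2 factor at 37 °C less that at 22 °C was -0.785, and -0.155 without the 834 genes raised at least 8-fold in both genotypes. The 834 genes were chosen for their rise in the same libraries, so the change largely restates their share of the counts. It fits a limited set of genes taking much of the counts but is no separate test of it. A fall of most genes under total-count scaling may reflect that share, although total RNA per plant was not measured.

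Among 5 sets of heat-responsive genes, each tested with and without A03 in 3 contrasts (30 tests), the 395 genes lowered at least 8-fold on average were singled out after all had been seen. Their median interaction log2 was 0.59, toward a smaller fall in gi, with camera adjusted p = 0.00814 at the preset correlation and adjusted p = 0.779 with an estimated correlation. For gi against wild type at 37 °C the median was 0.55 (camera adjusted p = 0.00666 and 0.779, fry adjusted p = 0.0452; without A03, 0.39 with 0.112, 0.995 and 0.782), and at 22 °C it was -0.03. For the interaction without A03 the median was 0.55 over 318 genes and the p with an estimated correlation was 0.35 (adjusted p = 0.995), so a smaller fall in gi may or may not exist and was not shown.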
